A study of Mus musculus with 12 samples.

How the data were processed

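The series measured RNA by sequencing in alveolar epithelial cells of C57BL/6 mice, in 12 libraries of 4 groups: saline, LPS for 1 day, bleomycin for 2 weeks and bleomycin for 4 weeks. Per the labels' protocols, lungs were digested, red cells were lysed, cells bound by antibodies against leukocyte (CD45 and CD16/32), endothelial (CD31), red cell (Ter119) and mesenchymal (CD90, PDGFRα) surface proteins were removed with magnetic beads, and EpCAM-positive cells were then kept. Total RNA was extracted with a column kit and libraries were made with the sequencer maker's standard protocol and sequenced on an Illumina instrument. HISAT2 (a read aligner) and StringTie (a transcript quantifier) are named, with genome build mm10 and without versions or roles, per the submitters' processing notes. The annotation release, the strand setting and the read totals are not given in the sources used here.

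The authors deposited 3 tables, each with the libraries of 1 treatment and of saline. Per the file headers, the deposited values per library are FPKM, that is, read fragments scaled by transcript length and by the library's total. The tables hold 13755 (LPS), 13984 (2 weeks) and 13667 (4 weeks) genes, all protein-coding, and each gene in them had a mean of at least 0.5 FPKM in 1 of its table's groups, so genes below that in both groups were not used here. 1 line of each table had been emptied in the copy used. The deposited group means named FPKM are log2(FPKM + 1) by their values, and the deposited log2 fold change is their difference; the deposited fold change is its linear ratio. The p-value deposited by the authors matched an equal-variance two-sample statistic on log2(FPKM + 1) to within 5.24e-12, and the deposited q-value differed from a Benjamini-Hochberg adjustment of it by up to 0.0825; how it was adjusted is not given in the sources used here. The saline values were identical in the 3 tables (largest difference 0), so the 13518 genes in all tables share 1 scale.

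Libraries were assigned to groups by sample title. In the 4-week group 1 column carried a number that matched no title; it was used as a library of that group without a number. No 2 libraries held identical values (highest correlation across genes 0.987). FPKM of a gene could not be traced to whole reads: among genes of a single exon, the share of low values within 0.1 of a multiple of 1 step was 30.8% to 45.2%, and only in 4-week library 1 (45.2% against up to 41.0%) and 4-week library 2 (44.4% against up to 40.0%) did it pass the highest of 20 shuffles of that library. Most values were not whole in any library, so depth is unknown and no interval for counting error can be given. Values of the 4-week group are given for each library, because library 2 of that group listed 45.4% of genes at 0, including 16.7% of those with the highest FPKM in the other two libraries, which may be failed estimates.

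Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, two-sided) on log2(FPKM + 1), among genes with at least 1 FPKM in at least 3 of the libraries in the fit, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Each treatment was compared with saline on the 6 libraries of its own table, and the 2 direct comparisons between treatments came from 1 fit of the 12 libraries. Fold changes are on the log2(FPKM + 1) scale and understate the change of genes near or below 1 FPKM. No replicate block was used. The tests, the 31 gene lists (pathways, and markers of the cell types that the lung and the isolation could hold) and the rule for named genes were fixed before the data were examined, as were the alternatives, apart from those named as added. The lists were tested with camera (limma) at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry, which asks whether the genes of a list move on balance in a single direction and, in its mixed form, whether they change in either direction. All list calls in the 5 comparisons lost their call with the estimated correlation. In the fits without library 2 only those of the acute phase list held, between LPS and 2 weeks (adjusted p = 0.00921) and, in the fit of 11 libraries, between LPS and saline (0.00789). A list needed 3 tested members for a test; Muc5ac, Trp63, Wt1, Alas2 and Slc4a1 of the lists were not analysed here, and single values of some other list members are not reported here. Spp1 is a marker of the macrophage list but is also made by injured epithelium and other cells.

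The named genes were the 6 largest changes in each direction in each comparison with saline (3 in each direct comparison) among genes past the threshold, with a group mean of at least 10 FPKM, no overlap between the groups' libraries and a standard symbol; the 3 members with the smallest adjusted p in each list that passed; 18 fixed genes; and the 2 most abundant markers of each cell type list. Other genes were named after their values were seen, as the called members of lists with few calls. Coordinates are those of the deposited tables, in mm10. Genes with near-identical copies (Saa1 and Saa2, Orm1 and its neighbours, the haemoglobin genes, the H2 genes, Gapdh and its pseudogenes) and overlapping genes may share reads, and their levels are uncertain.

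The method was tested on data simulated from the real libraries' means and spreads, with 200 genes and a list changed. At changes of 1 and 2 on the log2 scale it recovered 53% and 90% of changed genes for LPS against saline, 90% and 97% for 2 weeks, 0% and 0% for 4 weeks, 3% and 46% for 4 against 2 weeks and 3% and 41% for LPS against 2 weeks, with 4 of 158, 10 of 212, 0 of 0, 3 of 52 and 2 of 46 calls false. Rates with an outlying library or correlated genes were not tested. Overlaps of calls were compared with independent sets and 100 simulations of unchanged groups with the same saline libraries. Alternatives were a pseudocount of 0.1, a minimum of 5 FPKM, scaling to equal totals, median-ratio scaling, quantile normalization, array weights and a replicate block. Others were a 12-library fit, a log2 size limit of 1, no minimum, no trend, the authors' q-values, and leaving out each library compared. A fit of 11 libraries without library 2 and gene-by-gene array weights were added after seeing the data. Without counts, count-based tests were not used.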

Results

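RNA was sequenced from alveolar epithelial cells of C57BL/6 mice in 4 groups of 3 libraries each. The groups had received saline, lipopolysaccharide (LPS, a bacterial cell wall component that sets off acute lung inflammation) at 2 mg/kg 1 day earlier, or bleomycin (an anticancer drug used in mice to produce lung injury followed by fibrosis) at 1.5 U/kg either 2 weeks or 4 weeks earlier. All were given through the trachea. Epithelial cells were taken from digested lung by removing cells of other types and keeping cells positive for EpCAM, an epithelial surface protein. The labels do not say that the 3 libraries of a group came from separate animals, so p-values rest only on the spread between these samples, which may be technical. In limma the spread of a gene is also drawn toward that of all genes tested. Expression was deposited as FPKM (fragments scaled by transcript length and by the library total) without read counts, so the sequencing depth of each library is unknown. Over the 13518 genes shared by all tables, summed FPKM was 325720 to 336482 in saline, 329356 to 403757 after LPS, 288890 to 302083 at 2 weeks and 321518 to 369840 at 4 weeks of bleomycin. Libraries are called by group and number. 1 library of the 4-week group carried a number that matched no sample title and is called the unnumbered 4-week library.

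Library 2 of the 4-week group stood apart from all others. It listed 6142 of 13518 genes (45.4%) at 0 FPKM, against 1 to 78 genes in each of the other 11 libraries, and its median was 0.463 FPKM against 4.65 to 6.78. Epcam was listed at 0 in this library and at 20.7 to 46.2 FPKM in the others, while Eef1a1, a translation factor gene used by every cell, stood at 131 against 722 to 1270. Its 10 most abundant genes held 34.9% of summed FPKM, against 6.99% to 18.1% elsewhere. Its Pearson correlation across genes with the other 11 libraries was 0.537 to 0.628, whereas libraries of 1 group correlated at 0.978 to 0.986 in saline, 0.947 to 0.975 after LPS, 0.980 to 0.987 at 2 weeks and 0.974 for the remaining 4-week pair. Genes are not independent replicates. On the first principal component of the 12 libraries (68.1% of variance) it lay at 237 and the others at -36.6 to -2.76. Among the other 11 libraries, the first component (57.5%) placed the LPS libraries at 40.5 to 76.3 and all others at -34.3 to -15.6. The second (16.4%) placed the 2-week libraries at -35.6 to -27.8, saline at 19.6 to 27.2 and the 4-week pair at 15.1 and 3.41. The labels give no batch. Because of the zeros, 4-week values are given for each library.

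**Figure D1:**
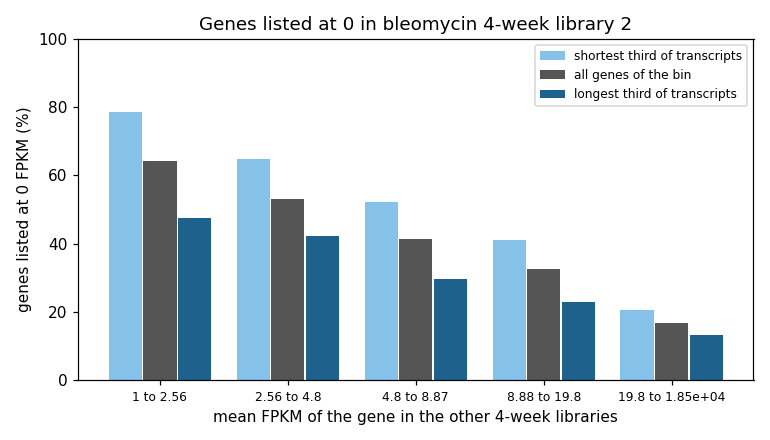
Percentage of genes listed at 0 FPKM in library 2 of the 4-week bleomycin group (vertical axis, %), in 5 bins of the gene's mean FPKM in the other 4-week libraries (horizontal axis), for the shortest tertile of transcripts, all genes and the longest tertile. The share over all genes falls from 64.4% in the lowest bin to 16.7% in the highest, and in each bin it is lower for the longest than for the shortest transcripts.

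The comparison of LPS with saline asked which transcripts of alveolar epithelial cells differed 1 day after the instillation. Acute phase and inflammatory transcripts were higher after LPS, and transcripts of AT2 cells (alveolar type 2 cells, which make surfactant) were lower. Saa3, which encodes an acute phase serum amyloid A protein, rose from 3.22 ± 0.615 to 2251 ± 988 FPKM (SD, n = 3 in each group), a log2 fold change of 8.95 ± 0.34 (SE, limma adjusted p = 2.66e-06). Orm1, the gene of an acute phase plasma glycoprotein, rose from 0.734 ± 0.170 to 319 ± 90.5 FPKM (log2 7.49 ± 0.23, limma adjusted p = 7.67e-07). Cxcl9, an interferon-induced chemokine gene, rose from 0.328 ± 0.171 to 120 ± 84.4 FPKM (log2 6.30 ± 0.41, limma adjusted p = 2.74e-05). Sftpc, the surfactant protein C gene, fell from 12002 ± 1856 to 3181 ± 1369 FPKM (log2 -2.01 ± 0.44, limma adjusted p = 0.00771). Hc, the complement C5 gene, fell from 122 ± 19.0 to 6.54 ± 2.01 FPKM (log2 -4.05 ± 0.22, limma adjusted p = 1.56e-05). In the mm10 coordinates of the deposited tables, Saa3 lies on chromosome 7 (46711998 to 46715700), Orm1 on chromosome 4 (63344560 to 63348163), Cxcl9 on chromosome 5 (92321347 to 92328079), Sftpc on chromosome 14 (70520941 to 70524081) and Hc on chromosome 2 (34983331 to 35061438). Orm1 and the Saa genes have near-identical neighbours with which reads may be shared, so their exact levels are uncertain. Among genes of at least 10 FPKM in the higher group, Ly6i (log2 6.11), Saa1 (6.02) and Ccl12 (5.75) came next upward, and Colq (-3.65), Scube2 (-3.21), Itga8 (-3.13), Cst8 (-3.11) and Abca8a (-3.08) downward.

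Of 12456 genes tested against saline, 1770 rose and 3232 fell after LPS (limma, Benjamini-Hochberg adjusted p under 0.05). In 55.7% of genes all 3 LPS libraries lay on the same side of all 3 saline libraries, where chance gives 10%. The median log2 fold change of all genes was -0.22. It became -0.37 with libraries scaled to equal totals, -0.02 with median-ratio scaling and -0.06 with quantile normalization, and the called genes then divided into 1218 and 3717, 2441 and 2195, and 2134 and 2546 that rose and fell. The total of 5002 came to 669 (398 rose, 271 fell) in 1 fit of 12 libraries with 1 shared spread. That fit gave 6183 without 4-week library 2. Totals were 2970, 2584 and 2561 without saline libraries 1, 2 and 3, 2979 without LPS library 3, and 2857 by the authors' q-values.

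Epithelial markers of several cell types fell after LPS. Whether leukocytes diluted these and other lists was not tested. Of 17 AT2 markers tested, 12 fell and 2 rose, with the same counts adjusted over the list alone (median log2 fold change -1.21, camera adjusted p = 0.00144, or 0.482 with an estimated correlation). Besides Hc and Sftpc, Etv5, a transcription factor gene of AT2 cells, fell from 54.9 ± 5.88 to 13.8 ± 2.96 FPKM (limma adjusted p = 0.000189) and Sftpb from 1601 ± 185 to 687 ± 213 FPKM (limma adjusted p = 0.0088). The 2 risers, named after their values were seen, were Sftpd (log2 0.96), a surfactant collectin of innate defence, and Ctsh (log2 0.76), a protease. The Sftpb call was lost with median-ratio scaling (adjusted p = 0.0512) and without saline library 2 (0.0514). Of 17 AT1 markers (alveolar type 1 cells, which line the air space for gas exchange), 8 fell and 1 rose, again the same over the list alone (median -0.82, camera adjusted p = 0.0361, or 0.697 with an estimated correlation). Emp2 fell from 207 ± 14.5 to 104 ± 20.6 FPKM and Pdpn, which encodes podoplanin, rose from 39.7 ± 10.3 to 86.3 ± 24.4 FPKM (limma adjusted p = 0.00493 and 0.0117). Ager, the gene of an AT1 membrane receptor, stood at 222 ± 70.2 and 165 ± 9.44 FPKM (adjusted p = 0.264). The AT1 call was lost without saline library 3 (adjusted p = 0.0841), LPS library 1 (0.0593) or LPS library 2 (0.122), with a pseudocount of 0.1 (0.0555), among genes of at least 5 FPKM (0.0632) and in the fit of 11 libraries (0.0505), and the Pdpn call without LPS library 3 (0.0545). Of 14 ciliated cell markers, 11 fell and 0 rose, or 12 and 0 over the list alone (median -0.64, camera adjusted p = 0.00213, or 0.486 with an estimated correlation). Ak7 fell from 16.7 ± 1.64 to 6.02 ± 1.62 FPKM. Of 16 genes of epithelial junctions, 12 fell and 0 rose, or 12 and 1 over the list alone (median -0.85, camera adjusted p = 0.00626, or 0.486 with an estimated correlation). Cdh1 fell from 68.5 ± 8.30 to 27.4 ± 7.53 FPKM, and Ocln from 9.06 ± 1.42 to 2.64 ± 1.01 FPKM. Epcam fell from 41.3 ± 4.21 to 23.2 ± 2.65 FPKM (limma adjusted p = 0.00584).

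The list of the transitional alveolar epithelium, a state described between AT2 and AT1 cells, moved both ways after LPS and did not pass as a list (median -0.08, test upward, camera adjusted p = 0.583). Of its 17 members, Krt8, Krt18, Cldn4, Sfn and Areg fell and Lgals3, Clu, Plaur and Tnip3 rose, or 5 and 5 over the list alone. Krt8, a keratin gene, fell from 205 ± 17.3 to 99.1 ± 25.8 FPKM and Lgals3, the galectin-3 gene, had a log2 fold change of 1.54. Of 12 club and goblet cell markers, 7 fell and 3 rose (median -0.90, camera adjusted p = 0.143), and the risers were the secreted proteins Scgb3a1 (log2 0.85) and Muc5b (0.84) and the mucin-folding enzyme Agr2 (2.02). Cbr2 fell from 1538 ± 194 to 432 ± 68.0 FPKM, and Scgb1a1, the club cell secretory protein gene, stood at 12305 ± 2220 in saline and 8330 ± 3302 FPKM after LPS (limma adjusted p = 0.296). Of 14 ion and water transport genes 3 rose and 6 fell (camera adjusted p = 0.784), with Slc12a2 (log2 -1.09), Atp1b1 (-0.88) and Scnn1b (-0.77) among those that fell. Only 2 basal cell markers were tested, too few for a list test. Aqp3 rose from 0.940 ± 0.416 to 3.12 ± 0.225 FPKM.

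Fatty acid synthesis genes fell after LPS. Of 16 genes of fatty acid and phospholipid synthesis, 14 fell and 0 rose, also over the list alone (median -0.91, camera adjusted p = 0.000609, or 0.486 with an estimated correlation). Scd1, which encodes a fatty acid desaturase, fell from 459 ± 102 to 93.9 ± 30.1 FPKM, and Fasn, the gene of fatty acid synthase, from 45.6 ± 3.18 to 17.9 ± 4.70 FPKM (limma adjusted p = 0.00044 and 0.00185). Of 19 genes of cholesterol synthesis 4 fell and 1 rose (median -0.35, camera adjusted p = 0.25). Of 16 genes of fatty acid oxidation 5 fell and 0 rose (median -0.09, camera adjusted p = 0.291). Insig1 of the cholesterol list (log2 -1.21) and Pdk4 of the oxidation list (-1.67) were among those that fell.

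Most genes of the inflammatory lists rose after LPS. Of 22 interferon-stimulated genes 20 rose and 0 fell, or 21 and 0 over the list alone (median 2.79, camera adjusted p = 4.44e-17, or 0.245 with an estimated correlation). Of 19 acute phase and antimicrobial genes 17 rose and 0 fell, or 18 and 0 over the list alone (median 2.11, camera adjusted p = 8.09e-16, or 0.0691 with an estimated correlation). Of 20 NF-kB targets and chemokines 17 rose and 0 fell, also over the list alone (median 1.72, camera adjusted p = 1.01e-13, or 0.189 with an estimated correlation). Of 18 antigen presentation genes 12 rose and 0 fell, also over the list alone (median 1.18, camera adjusted p = 2.05e-08, or 0.402 with an estimated correlation). Rsad2, the gene of the antiviral enzyme viperin, rose from 2.14 ± 0.690 to 68.8 ± 27.8 FPKM. Lcn2, which encodes the iron-scavenging protein lipocalin 2, rose from 72.2 ± 16.9 to 1544 ± 458 FPKM (limma adjusted p = 2.91e-05). Csf3, the gene of the neutrophil growth factor G-CSF, rose from 0.448 ± 0.123 to 58.0 ± 5.80 FPKM, and Cxcl1, a chemokine gene for neutrophils, from 80.6 ± 7.87 to 258 ± 84.8 FPKM. Cd274, the gene of the immune checkpoint ligand PD-L1, rose from 7.26 ± 3.06 to 97.1 ± 24.0 FPKM.

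Transcripts of leukocytes moved with the inflammatory groups, although leukocytes had been depleted with CD45 and CD16/32 antibodies. Of 14 neutrophil markers 12 rose and 0 fell, also over the list alone (median 3.09, camera adjusted p = 5.69e-12, or 0.245 with an estimated correlation). S100a9 rose from 260 ± 109 to 2694 ± 1313 FPKM and Il1b from 129 ± 47.7 to 1454 ± 321 FPKM. Of 17 macrophage and monocyte markers 14 rose and 0 fell, also over the list alone (median 2.18, camera adjusted p = 1.84e-12, or 0.189 with an estimated correlation). Marco, a scavenger receptor gene, rose from 2.21 ± 0.912 to 87.4 ± 20.8 FPKM and Adgre1, the gene of F4/80, from 5.11 ± 1.14 to 49.4 ± 9.22 FPKM. Ptprc, the gene of CD45, stood at 6.32 ± 1.25 and 9.77 ± 2.67 FPKM (limma adjusted p = 0.0869).

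Metabolic and stress groups changed too. Of 17 glycolysis genes, 12 rose and 1 fell, also over the list alone (median 0.64, camera adjusted p = 6.11e-06, or 0.189 with an estimated correlation). Pkm, the gene of a pyruvate kinase, rose from 139 ± 4.74 to 384 ± 86.0 FPKM, and the faller was Pdk1 (log2 -0.82), a kinase that holds back pyruvate oxidation. Of 24 genes of oxidative phosphorylation, 8 rose and 0 fell, also over the list alone (median 0.44, camera adjusted p = 2.26e-05, or 0.245 with an estimated correlation). Cox5a rose from 92.6 ± 3.27 to 214 ± 62.0 FPKM. Of 20 genes of the unfolded protein response, 8 rose and 1 fell, also over the list alone (median 0.35, camera adjusted p = 0.00122, or 0.189 with an estimated correlation and 0.0825 with quantile normalization). Sdf2l1, which encodes a chaperone partner of the endoplasmic reticulum, rose from 19.0 ± 2.66 to 73.9 ± 3.20 FPKM. Of 17 cell cycle genes, 6 rose and 0 fell, also over the list alone (median 0.41, camera adjusted p = 0.00626, or 0.583 with an estimated correlation and 0.174 among genes of at least 5 FPKM). Mki67, a gene of dividing cells, rose from 1.35 ± 0.373 to 3.93 ± 0.877 FPKM. Of 17 p53 targets, Cdkn1a, Bax, Pmaip1, Fas and Aen rose and Sesn1, Trp53inp1, Perp and Polk fell (median -0.12, test upward, camera adjusted p = 0.56). Bax had a log2 fold change of 1.44 and Cdkn1a one of 0.70, a call lost with equal totals (adjusted p = 0.0847), with quantile normalization (0.329), with the replicate number as a block (0.0515) and without saline library 2 (0.143), saline library 3 (0.144) or LPS library 3 (0.107). Matrix and TGF-beta response genes also divided, with 5 that rose and 6 that fell (camera adjusted p = 0.25), among them Timp1 (log2 4.41), a metalloproteinase inhibitor gene, and Lama3 (-1.55), a laminin gene of the basement membrane.

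Immediate early and clock genes were lower after LPS than in saline. Of 13 immediate early and dissociation stress genes, 8 fell and 0 rose, also over the list alone (median -0.90, camera adjusted p = 0.000873, or 0.245 with an estimated correlation). Egr1 fell from 567 ± 33.4 to 183 ± 44.1 FPKM. Of 15 circadian clock genes, 10 fell and 1 rose, also over the list alone (median -0.85, camera adjusted p = 0.00626, or 0.486 with an estimated correlation). Nr1d1, a repressor in the clock, fell from 56.0 ± 12.6 to 9.21 ± 3.16 FPKM and the riser was Cry1 (log2 0.67). None of 13 mitochondrially encoded genes passed (limma, median -0.54, camera adjusted p = 0.36). Their level was -1.53 relative to saline in LPS library 2 and -0.05 in each of the other two libraries.

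Of 16 fibroblast and smooth muscle markers, 9 fell and 1 rose, or 10 and 1 over the list alone (median -0.70, camera adjusted p = 0.00778, or 0.486 with an estimated correlation). Inmt, a methyltransferase gene, fell from 1437 ± 132 to 286 ± 104 FPKM and Thy1 rose (log2 0.94). Of 5 mesothelial markers 4 fell and 0 rose, also over the list alone (median -1.65, camera adjusted p = 0.026, or 0.486 with an estimated correlation). Upk1b fell from 38.5 ± 1.68 to 8.88 ± 2.13 FPKM. That call was lost without LPS library 1 (0.0597) or LPS library 2 (0.0540) and in the fit of 11 libraries (0.0505). Of the lymphocyte markers, the B cell genes Cd79a, Cd79b and Ms4a1 fell (log2 -1.42 to -1.21). The T and natural killer cell genes Cd3g, Cd8a, Nkg7 and Gzma rose (log2 0.67 to 1.52), and the list as a whole did not pass (camera adjusted p = 0.11). Cd79a lost its call without LPS library 3 (adjusted p = 0.0891). Of the endothelial markers 3 fell, Kdr (log2 -1.53), Tie1 (-0.74) and Tek (-1.15), and the list did not pass (camera adjusted p = 0.348). Of 4 erythroid genes none passed (limma, camera adjusted p = 0.14), with Hbb-bs at 47.3 ± 35.0 and 71.3 ± 22.7 FPKM.

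The comparison of 2 weeks of bleomycin with saline asked which transcripts differed in the weeks in which fibrosis develops in this model. Matrix, macrophage and cell division transcripts were higher and AT2 transcripts were lower. Spp1, the gene of the matrix protein osteopontin, rose from 39.6 ± 2.17 to 1239.7 ± 71.4 FPKM (SD, n = 3 in each group; log2 4.93 ± 0.08, limma adjusted p = 8.41e-07). Thbs4, a thrombospondin gene, rose from 0.245 ± 0.0808 to 38.5 ± 3.34 FPKM (log2 4.99 ± 0.10, limma adjusted p = 1.4e-06). Tnc, the tenascin C gene, rose from 5.77 ± 1.56 to 114 ± 11.7 FPKM (log2 4.10 ± 0.16, limma adjusted p = 3.61e-05). Bex2, of a family of small adaptor proteins, fell from 63.1 ± 13.0 to 2.99 ± 0.934 FPKM (log2 -4.01 ± 0.21, limma adjusted p = 7.48e-05). Sftpc fell from 12002 ± 1856 to 2993 ± 490.0 FPKM (log2 -2.01 ± 0.18, limma adjusted p = 0.000412), although the call was lost with quantile normalization (log2 -0.38, adjusted p = 0.262). In mm10, Spp1 lies on chromosome 5 (104435118 to 104441050), Thbs4 on chromosome 13 (92751590 to 92794818), Tnc on chromosome 4 (63959785 to 64047015) and Bex2 on chromosome X (136066564 to 136068236). Saa3 (log2 3.96), Fst (3.79) and C1qb (3.53) came next upward, and Cst8 (-3.34), Acoxl (-2.80), Bex4 (-2.78), Igfbp3 (-2.65) and Nrn1 (-2.30) downward.

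Of 12725 genes tested, 2290 rose and 1496 fell at 2 weeks (limma, Benjamini-Hochberg adjusted p under 0.05). The libraries did not overlap in 47.3% of genes, where chance gives 10%. The median log2 fold change was 0.05 and became 0.18 with libraries scaled to equal totals, and the genes that rose and fell numbered 3657 and 917 with equal totals, 2012 and 1971 with median-ratio scaling and 1925 and 2027 with quantile normalization. The total of 3786 came to 2153 without 2-week library 3 and to 2498 without saline library 3. The single fit of all 12 libraries called 134 genes for this comparison (97 rose, 37 fell) and no longer called Spp1 (adjusted p = 0.0830), and a fit of 11 libraries without 4-week library 2 called 1773.

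AT2 transcripts fell at 2 weeks. Of 17 AT2 markers 15 fell and 0 rose, or 16 and 0 over the list alone (median -1.51, camera adjusted p = 4.07e-13, or 0.31 with an estimated correlation). Sftpa1, a surfactant protein gene, fell from 1272 ± 165 to 319 ± 11.2 FPKM and Sftpb from 1601 ± 185 to 510.1 ± 46.7 FPKM. Lamp3, of the lamellar bodies that store surfactant, fell from 219 ± 32.7 to 62.9 ± 13.7 FPKM and Abca3, a lipid pump of the same bodies, from 64.9 ± 5.90 to 23.9 ± 0.726 FPKM (limma adjusted p = 0.000106 to 0.000601). Of 17 AT1 markers, Hopx, Cav1, Emp2, Clic5 and Vegfa fell and Pdpn and Agrn rose, or 6 and 2 over the list alone (median -0.45, camera adjusted p = 0.00634, or 0.627 with an estimated correlation and 0.0551 without saline library 3). Hopx fell from 177 ± 49.9 to 81.8 ± 14.1 FPKM, Pdpn rose from 39.7 ± 10.3 to 84.3 ± 13.4 FPKM, and Ager stood at 222 ± 70.2 and 127 ± 15.7 FPKM (limma adjusted p = 0.052). Transitional epithelium genes again moved both ways (camera adjusted p = 0.903; median 0.11, test downward): Krt8, Krt18, Krt19, Sfn, Areg and Hbegf fell and Lgals3, Ndrg1, Sprr1a, Clu, Gdf15 and Tnip3 rose. Krt8 fell from 205 ± 17.3 to 125 ± 9.65 FPKM (limma adjusted p = 0.00192). Cldn4 stood at 24.3 ± 10.7 and 24.3 ± 0.829 FPKM and Cdkn1a at 138 ± 31.3 and 177 ± 14.7 FPKM (limma adjusted p = 0.841 and 0.114).

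Airway and junction genes were lower at 2 weeks. Of 12 club and goblet cell markers, 9 fell and 0 rose, or 10 and 0 over the list alone (median -1.06, camera adjusted p = 8.95e-06, or 0.31 with an estimated correlation). Scgb1a1 fell from 12305 ± 2220 to 4954 ± 1532 FPKM (limma adjusted p = 0.0081) but had a log2 fold change of 0.12 with quantile normalization, and Cyp4b1, a cytochrome P450 gene, fell from 153 ± 11.7 to 57.8 ± 9.36 FPKM. Of 14 ciliated cell markers, 8 fell and 0 rose, or 9 and 0 over the list alone (median -0.38, camera adjusted p = 3.92e-05, or 0.322 with an estimated correlation). Tppp3 fell from 171 ± 5.83 to 84.3 ± 4.01 FPKM. Of 16 junction genes, 8 fell and 0 rose, or 12 and 0 over the list alone (median -0.45, camera adjusted p = 1.38e-05, or 0.31 with an estimated correlation). Cldn7, a claudin gene, fell from 29.5 ± 2.19 to 14.8 ± 0.773 FPKM. Epcam fell from 41.3 ± 4.21 to 27.7 ± 4.19 FPKM (limma adjusted p = 0.0166; 0.0549 without saline library 2). Of 14 ion and water transport genes 4 rose and 4 fell (camera adjusted p = 0.11), with Cftr (log2 -0.90) and Slc26a9 (-1.36), which encode chloride channels, among the fallers. Of 4 basal cell markers Krt5 (log2 1.27) and Aqp3 (0.89) rose and 0 fell (camera adjusted p = 0.308).

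Genes of fatty acid and cholesterol synthesis fell at 2 weeks. Of 16 fatty acid and phospholipid synthesis genes, 10 fell and 2 rose, or 11 and 2 over the list alone (median -0.47, camera adjusted p = 6.4e-05, or 0.31 with an estimated correlation). Fasn fell from 45.6 ± 3.18 to 19.8 ± 1.99 FPKM (limma adjusted p = 0.000324), and the risers were the elongase gene Elovl6 (log2 1.25) and the desaturase gene Fads2 (0.57). Of 19 cholesterol synthesis genes, 10 fell and 0 rose, or 11 and 0 over the list alone (median -0.31, camera adjusted p = 8.95e-06, or 0.322 with an estimated correlation). Insig1, a sterol sensor gene, fell from 60.1 ± 3.20 to 29.9 ± 2.82 FPKM. Of 16 genes of fatty acid oxidation 6 fell and 0 rose (camera adjusted p = 0.0737). Of 17 glycolysis genes, 9 rose and 0 fell, or 9 and 1 over the list alone (median 0.29, camera adjusted p = 0.0239, or 0.31 with an estimated correlation). Pgam1 rose from 40.5 ± 0.959 to 65.1 ± 3.94 FPKM. None of 24 oxidative phosphorylation genes passed (limma, camera adjusted p = 0.798). In contrast, 12 of 13 mitochondrially encoded genes fell and 0 rose, also over the list alone (median -0.58, camera adjusted p = 2.06e-07, or 0.31 with an estimated correlation). With quantile normalization the mitochondrial list no longer passed (median -0.15, adjusted p = 0.187). Mt-Nd2 stood at 1801 ± 82.4 and 952 ± 104 FPKM, a call lost with quantile normalization (0.0565) and in the fit of 11 libraries (0.169).

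All 25 cell cycle genes rose at 2 weeks, also over the list alone (median 1.34, camera adjusted p = 3.97e-15, or 0.31 with an estimated correlation). Top2a, the gene of a topoisomerase needed in dividing cells, rose from 1.46 ± 0.322 to 8.75 ± 1.03 FPKM and Mki67 from 1.35 ± 0.373 to 7.92 ± 0.704 FPKM (limma adjusted p = 0.000156 and 0.000187). Of 18 p53 targets, 9 rose and 0 fell, or 10 and 0 over the list alone (median 0.38, camera adjusted p = 0.00127, or 0.31 with an estimated correlation). Phlda3 rose from 29.3 ± 1.84 to 78.8 ± 2.25 FPKM and Eda2r from 0.689 ± 0.0338 to 3.51 ± 0.460 FPKM. Of 20 unfolded protein response genes 4 rose and 3 fell (camera adjusted p = 0.602). Of 13 immediate early and dissociation stress genes 11 fell and 0 rose, also over the list alone (median -0.84, camera adjusted p = 4.54e-07, or 0.322 with an estimated correlation). Atf3 fell from 699 ± 58.5 to 268 ± 48.3 FPKM. Of 15 clock genes Arntl, Npas2, Cry2 and Nr1d1 fell and 0 rose, or 2 fell over the list alone (median -0.19, camera adjusted p = 0.00916, or 0.31 with an estimated correlation and 0.0834 among genes of at least 5 FPKM). Nr1d1 lost its call with equal totals (0.0609), with the replicate block (0.0838), in the fit of 11 libraries (0.0697) and without 2-week library 1 (0.0942), 2-week library 2 (0.112), saline library 1 (0.0956) or saline library 2 (0.110), and Npas2 in the fit of 11 libraries (0.0501).

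Matrix and fibroblast transcripts rose together at 2 weeks, beside a rise of macrophage markers. Of 20 matrix and TGF-beta response genes, 14 rose and 1 fell, or 15 and 1 over the list alone (median 0.85, camera adjusted p = 8.95e-06, or 0.31 with an estimated correlation). Fn1, the fibronectin gene, rose from 65.1 ± 7.75 to 332 ± 0.195 FPKM, Timp1 from 47.6 ± 7.42 to 400 ± 35.2 FPKM, and the faller was Cyr61 (log2 -0.52). Of 16 fibroblast and smooth muscle markers, 10 rose and 1 fell, also over the list alone (median 0.71, camera adjusted p = 0.00507, or 0.322 with an estimated correlation). Col1a1, a collagen I gene on chromosome 11 (94936224 to 94953042), rose from 148 ± 30.8 to 579 ± 37.9 FPKM (log2 1.98 ± 0.15, limma adjusted p = 0.000246). Inmt fell from 1437 ± 132 to 363 ± 98.6 FPKM, and Acta2, the gene of smooth muscle actin, stood at 425 ± 167 and 411 ± 17.2 FPKM (limma adjusted p = 0.941). Of 17 macrophage and monocyte markers 12 rose and 0 fell, also over the list alone (median 1.91, camera adjusted p = 2.06e-07, or 0.322 with an estimated correlation). C1qb, a complement gene of tissue macrophages on chromosome 4 (136880129 to 136886187), rose from 18.9 ± 0.199 to 232 ± 47.5 FPKM (log2 3.53 ± 0.15, limma adjusted p = 3.85e-05). Chil3, abundant in alveolar macrophages, stood at 143 ± 41.7 and 155 ± 51.7 FPKM and Ptprc at 6.32 ± 1.25 and 7.66 ± 1.40 FPKM (limma adjusted p = 0.794 and 0.319).

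Inflammatory lists rose in part at 2 weeks. Of 22 interferon-stimulated genes, 7 rose and 0 fell, also over the list alone (median 0.39, camera adjusted p = 0.00507, or 0.627 with an estimated correlation and 0.108 without 2-week library 1). Of 17 acute phase genes, 7 rose and 0 fell, or 9 and 1 over the list alone (median 0.46, camera adjusted p = 0.00323, or 0.31 with an estimated correlation). Saa3 rose from 3.22 ± 0.615 to 64.2 ± 6.54 FPKM and Lcn2 stood at 72.2 ± 16.9 and 97.9 ± 7.69 FPKM (limma adjusted p = 0.0879). Of 20 NF-kB targets and chemokines 5 rose and 1 fell, or 10 and 3 over the list alone (camera adjusted p = 0.26). Ccl2, a monocyte chemokine gene, had a log2 fold change of 1.40. Of 18 antigen presentation genes the class II genes H2-Eb1, H2-DMa and H2-DMb1 rose and 0 fell, or 1 and 0 over the list alone (median 0.34, camera adjusted p = 0.049, or 0.744 with an estimated correlation). The list call was lost with a pseudocount of 0.1 (0.0575), among genes of at least 5 FPKM (0.0866), with median-ratio scaling (0.0537) and without 2-week library 1 (0.476), saline library 2 (0.141) or saline library 3 (0.170). Without 2-week library 1, 2-week library 2, saline library 2 or saline library 3, H2-DMa and H2-Eb1 no longer passed (adjusted p = 0.0863 to 0.137), and H2-DMb1 had 0.0544 without saline library 3. H2-DMa and H2-Eb1 also lost their calls with median-ratio scaling (0.0505 and 0.0787) and in the fit of 11 libraries (0.0673 and 0.0728). Of 11 neutrophil markers Mmp8 rose (log2 1.27) and S100a9 fell, from 260 ± 109 to 99.1 ± 24.0 FPKM (camera adjusted p = 0.395). The S100a9 call was lost in the fit of 11 libraries (adjusted p = 0.0678), with the replicate block (0.0662) and without 2-week library 1 (0.0854), 2-week library 3 (0.0955), saline library 1 (0.0760) or saline library 3 (0.0966). Of 15 lymphocyte markers Cd3e (log2 1.02), Cd3g (1.04) and Cd4 (0.95) rose and 0 fell (median -0.07, test upward, camera adjusted p = 0.798). Of 12 endothelial markers Kdr fell (log2 -0.68, camera adjusted p = 0.052), and 0 of 5 mesothelial markers passed (limma, camera adjusted p = 0.581). Of 4 erythroid genes 0 passed over all genes tested and 4 fell over the list alone (median -1.31, camera adjusted p = 0.029, or 0.506 with an estimated correlation, 0.0539 with median-ratio scaling, 0.0603 with quantile normalization and 0.0591 without 2-week library 1). Saline library 1 stood 1.04 above the saline mean on that list.

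**Figure D2:**
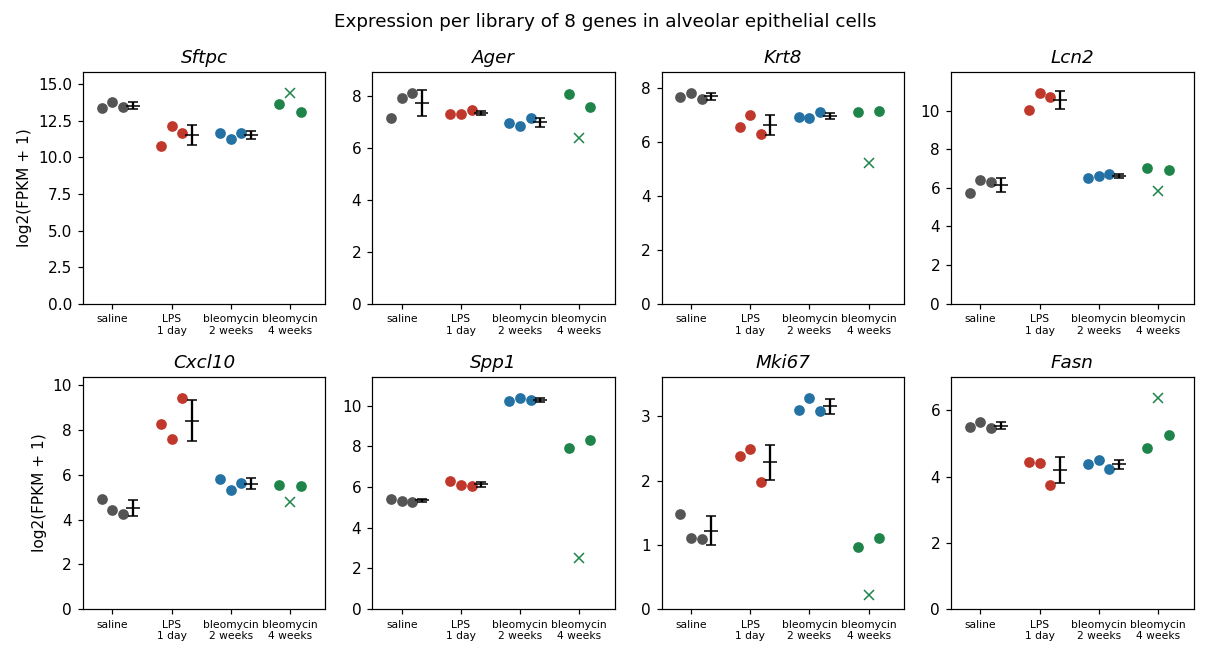
Expression of Sftpc, Ager, Krt8, Lcn2, Cxcl10, Spp1, Mki67 and Fasn in each library (vertical axis, log2(FPKM + 1); horizontal axis, group). Dots are libraries, the cross is library 2 of the 4-week group, and black bars are the mean ± SD of 3 libraries, not drawn for the 4-week group. Sftpc is lower after LPS and at 2 weeks than in saline, and Spp1 is highest at 2 weeks.

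The comparison of 4 weeks of bleomycin with saline asked which transcripts still differed at the later time. With all 3 libraries no gene passed, and the values of library 2 lay far from those of the other two 4-week libraries for most genes. C1qb stood at 76.2, 77.5 and 74.0 FPKM in library 1, library 2 and the unnumbered library, against 18.9 ± 0.199 FPKM in saline (SD, n = 3; log2 1.95 ± 0.31, limma adjusted p = 0.541). Spp1 stood at 237, 4.75 and 316 FPKM against 39.6 ± 2.17 in saline, Saa3 at 45.5, 6.92 and 28.7 FPKM against 3.22 ± 0.615, and Sftpc at 12988, 21625 and 8895 FPKM against 12002 ± 1856. Of 12325 genes tested limma called 0, with 302 at an unadjusted p under 0.05 and a smallest adjusted p of 0.541. The authors' deposited table gives 1 gene with a q under 0.05, C1qb (q = 0.000679). The median log2 fold change was -0.64, which became -0.43 with median-ratio scaling and 0.01 with quantile normalization. The lists that passed, with 0 genes called in each by limma, were acute phase (median 0.21, camera adjusted p = 3.76e-05), cholesterol synthesis (-0.97; 0.00254), neutrophil (-1.63; 0.00254), matrix (median -0.56, test upward; 0.0107) and macrophage (median -0.47, test upward; 0.0189). Each had an adjusted p = 0.957 with an estimated correlation. All 5 calls were lost without the unnumbered library (0.0698 to 0.254) and with the replicate block, which leaves out that library and saline library 3 (0.0658 to 0.519), and all but the acute phase call without library 1 (0.0574 to 0.163). The matrix and macrophage calls were lost with median-ratio scaling (0.0852 and 0.102), the matrix call with quantile normalization (0.410), and the macrophage call with a pseudocount of 0.1 (0.0537) and without saline library 2 (0.0919).

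Without library 2, a choice made after the data were seen, 97 genes rose and 80 fell among 12284 tested (limma, Benjamini-Hochberg adjusted p under 0.05; 2600 at an unadjusted p under 0.05). The test then rested on 2 libraries of 1 group against 3 of the other. Spp1 rose (log2 2.76 ± 0.15, limma adjusted p = 0.00334), as did Saa3 (3.15 ± 0.22; 0.00433), Tnc (2.30; 28.1 and 36.1 FPKM against 5.77 ± 1.56) and Ltbp2 (2.33; 59.6 and 67.8 FPKM against 11.9 ± 1.74), which encodes a latent TGF-beta binding protein. Bex2 fell (log2 -2.64; 10.7 and 7.72 FPKM against 63.1 ± 13.0) and Mapt, the tau gene, fell (-2.43; 1.78 and 4.03 FPKM against 19.3 ± 2.54). Of 16 macrophage markers 4 rose and 0 fell, or 5 and 0 over the list alone (median 0.53, camera adjusted p = 1.78e-06, or 0.63 with an estimated correlation). Of 16 fibroblast markers 2 rose and 0 fell, or 7 and 1 over the list alone (median 0.39, camera adjusted p = 1.96e-06, or 0.616 with an estimated correlation). Col3a1 rose, at 414 and 393 FPKM against 163 ± 38.9. Of 20 matrix genes 4 rose and 0 fell, or 7 and 0 over the list alone (median 0.27, camera adjusted p = 4.97e-06, or 0.63 with an estimated correlation). Fn1 rose, at 134 and 171 FPKM against 65.1 ± 7.75. Of 19 NF-kB targets Cxcl1, Ccl2 and Il6 rose and 0 fell, or 5 and 0 over the list alone (median 0.15, camera adjusted p = 0.00306, or 0.631 with an estimated correlation). Of 19 cholesterol synthesis genes 15 fell and 0 rose over the list alone (median -0.54, camera adjusted p = 1.78e-06, or 0.631 with an estimated correlation). Of 17 AT2 markers Etv5 fell, at 22.8 and 27.1 FPKM against 54.9 ± 5.88, and 0 rose, or 6 and 0 over the list alone (median -0.44, camera adjusted p = 0.00151, or 0.631 with an estimated correlation). Of 11 neutrophil markers Mmp9 fell and 0 rose, or 7 and 0 over the list alone (median -1.04, camera adjusted p = 0.00261, or 0.631 with an estimated correlation). Acute phase genes (median 0.32, camera adjusted p = 1.02e-05), p53 targets (0.16; 0.00746), mitochondrially encoded genes (0.41; 8.27e-06), unfolded protein response (0.05; 0.0141) and basal cell markers (0.58; 0.00746) passed upward. Fatty acid synthesis (median -0.41, camera adjusted p = 0.00805), junctions (-0.45; 0.00626), ciliated cells (-0.37; 0.00306), endothelium (-0.64; 0.013), clock (-0.31; 0.013) and immediate early genes (-0.30; 0.013) passed downward. In each of these 11 lists limma called at most 1 gene, and the lists had an adjusted p = 0.616 to 0.672 with an estimated correlation. Sftpc (log2 -0.15), Ager (0.11) and Mki67 (-0.19) did not pass (limma adjusted p = 0.772, 0.854 and 0.5).

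**Figure D3:**
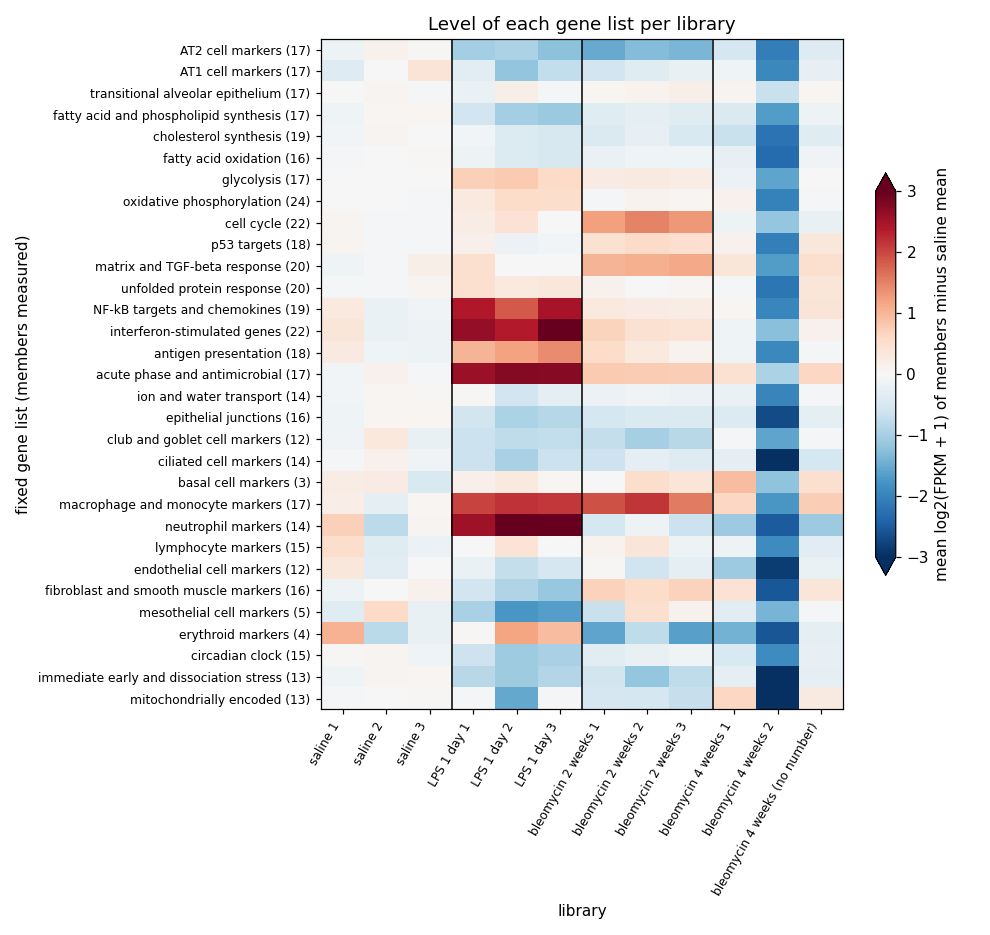
Level of the 31 gene lists (vertical axis, with the number of members measured) in each of the 12 libraries (horizontal axis), as the mean log2(FPKM + 1) of the members minus the saline mean. The colour scale ends at -3 and 3. Macrophage markers stand between 1.56 and 2.18 above saline in each LPS and 2-week library. Neutrophil markers stand high after LPS alone (2.55 to 3.23). Library 2 of the 4-week group is below saline on all lists (-3.28 to -0.67).

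The direct comparison of 4 with 2 weeks of bleomycin, in a fit of all 12 libraries, asked which transcripts changed between the times. Sftpc was higher at 4 weeks, at 12988, 21625 and 8895 FPKM in library 1, library 2 and the unnumbered library, than at 2 weeks, at 2993 ± 490.0 FPKM (SD, n = 3; log2 2.19 ± 0.38, limma adjusted p = 0.0306). Cox6a2, a cytochrome oxidase subunit gene on chromosome 7 (128205435 to 128206387), stood at 33.8, 39.0 and 20.8 FPKM against 5.95 ± 1.48 (log2 2.19, limma adjusted p = 0.0107). Npw, a neuropeptide gene on chromosome 17 (24657330 to 24658457), stood at 20.2, 24.6 and 20.2 FPKM against 4.93 ± 1.14 (log2 1.95, adjusted p = 0.0203). Arg1, the arginase 1 gene on chromosome 10 (24915208 to 24927470), was lower, at 1.13, 0 and 1.97 FPKM against 12.7 ± 5.30 (log2 -2.83, limma adjusted p = 0.0109). The mitotic genes Ccnb2 on chromosome 9 (70407689 to 70421554) and Cdc20 on chromosome 4 (118432901 to 118437352) stood at 2.20, 0 and 2.17 FPKM against 12.3 ± 2.02 and at 3.55, 0 and 2.27 FPKM against 13.1 ± 1.30. Their log2 fold changes were -2.60 and -2.52 (limma adjusted p = 0.0203 and 0.0494). Cdc20 overlaps the end of Elovl1, so its level may hold reads of that gene. Without any 1 of the 2-week libraries each of these 6 genes lost its call (adjusted p = 0.0623 to 0.353), as it did with the replicate block (0.0523 to 0.0719). Sftpc also lost it with quantile normalization (log2 0.32, adjusted p = 0.491), median-ratio scaling (0.0850) and a pseudocount of 0.1 (0.142), among genes of at least 5 FPKM (0.0790) and without 4-week library 1 (0.0718). With a pseudocount of 0.1 the other calls were lost except that of Cox6a2 (0.0783 to 0.274). Among genes of at least 5 FPKM, Ccnb2 (0.0562) and Cdc20 (0.118) lost theirs, as did Cdc20 with median-ratio scaling (0.0708) and Npw without 4-week library 1 (0.0525). Of 12822 genes tested 3 were higher and 64 lower at 4 weeks (limma, Benjamini-Hochberg adjusted p under 0.05). The median log2 fold change was -0.67, which became -0.83 with equal totals, -0.44 with median-ratio scaling and 0.02 with quantile normalization, where 34 were higher and 75 lower. Without library 2 the counts were 142 and 497, without the unnumbered library the total was 252, and without 2-week libraries 1, 2 and 3 it was 9, 1 and 9.

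Cell cycle genes were lower at 4 than at 2 weeks. Of 22 tested 17 were lower and 0 higher at 4 weeks, or 21 and 0 over the list alone (median -1.83, camera adjusted p = 7.48e-20, or 0.396 with an estimated correlation). The 17 became 4, 0 and 3 without 2-week libraries 1, 2 and 3, 0 with the replicate block, 1 with a pseudocount of 0.1, 7 with quantile normalization and 7 among genes of at least 5 FPKM, while the list call held in each (camera adjusted p up to 1.13e-07). Without library 2 they were 20 and 0 (median -1.63, camera adjusted p = 2.49e-27, or 0.0734 with an estimated correlation). Among 17 AT2 markers only Sftpc was called, as higher, or 2 over the list alone (median 0.31, camera adjusted p = 4.29e-09, or 0.396 with an estimated correlation). Without library 2, 9 AT2 markers were higher and 0 lower, or 13 and 0 over the list alone (median 1.08, camera adjusted p = 7.93e-19, or 0.0734 with an estimated correlation). The medians of AT2 and of club and goblet markers were below 0 without 4-week library 1 (-0.11 and -0.08) or the unnumbered library (-0.30 and -0.23), with tests still upward. Of 17 macrophage markers Fcgr1 was lower (not without 4-week library 1 or any 1 of the 2-week libraries), or 14 over the list alone (median -2.24, camera adjusted p = 9.13e-06, or 0.978 with an estimated correlation). Without library 2, 11 macrophage markers were lower (median -1.38, camera adjusted p = 2.43e-10, or 0.212 with an estimated correlation). Spp1 then stood at 237 and 316 FPKM against 1239.7 ± 71.4 (log2 -2.17, limma adjusted p = 0.000116). Of 12 club and goblet cell markers 0 were called over all genes (limma) and 3 were higher over the list alone (median 0.15, camera adjusted p = 7.28e-06, or 0.459 with an estimated correlation), a list call lost with quantile normalization (0.110). The mitochondrially encoded genes had a median of -0.12 but a test upward (camera adjusted p = 0.000558, or 0.978 with an estimated correlation), lost without 4-week library 1 (0.158) and with quantile normalization (median -0.72, test downward, 0.324). Without library 2 their median was 0.95.

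The direct comparison of LPS with 2 weeks of bleomycin asked which transcripts separated the acute from the later injury. Ly6i, a lymphocyte antigen 6 family gene on chromosome 15 (74979534 to 74983430), stood at 332 ± 90.5 FPKM after LPS and 3.10 ± 0.737 at 2 weeks (SD, n = 3 in each group; log2 6.32 ± 0.35, limma adjusted p = 1.95e-05), and Orm1 at 319 ± 90.5 and 4.61 ± 1.93 (log2 5.84, adjusted p = 1.95e-05). Acod1, the gene of an itaconate-making enzyme of activated macrophages on chromosome 14 (103046977 to 103056573), stood at 404 ± 79.7 and 6.67 ± 1.88 (log2 5.73, adjusted p = 0.000518). The matrix genes Fmod (1.50 ± 0.501 and 52.9 ± 4.92 FPKM; log2 -4.44), Cilp (1.08 ± 0.571 and 41.3 ± 3.27; -4.38) and Ltbp2 (5.26 ± 1.92 and 94.0 ± 4.76; -3.97) were lower after LPS (limma adjusted p = 0.000207, 0.0236 and 0.000596). Cilp lost its call with a pseudocount of 0.1 (0.178) and without any 1 of the LPS or 2-week libraries (0.0506 to 0.126). Of 12822 genes 221 were higher and 263 lower after LPS (limma, Benjamini-Hochberg adjusted p under 0.05). The median log2 fold change was -0.26, and the counts were 176 and 520 with equal totals (median -0.53), 327 and 222 with median-ratio scaling (-0.07), and 585 and 584 with quantile normalization (-0.01), which kept 380 of the 484 calls. Among genes of at least 5 FPKM they were 200 and 162, and without LPS library 2 or 3 or any 1 of the 2-week libraries 52.5% to 63.9% of the called genes were higher after LPS, so neither direction led in all settings. The total of 484 became 240 without LPS library 2, 169 without LPS library 3, 183, 173 and 119 without 2-week libraries 1, 2 and 3, and 5764 (1609 higher, 4155 lower) without 4-week library 2, which enters only through the shared spread.

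Interferon-stimulated genes separated the treatments, with 13 of 22 higher after LPS and 0 lower, or 20 and 0 over the list alone (median 2.18, camera adjusted p = 5.2e-28, or 0.0542 with an estimated correlation). Acute phase genes were 6 higher of 17 and 0 lower, or 11 and 0 over the list alone (median 1.16, camera adjusted p = 1.71e-16, or 0.0515 with an estimated correlation, and 0.00921 without 4-week library 2). Of 19 NF-kB targets 8 were higher and 0 lower, or 12 and 0 over the list alone (median 1.51, camera adjusted p = 5.08e-17, or 0.0923 with an estimated correlation). Neutrophil markers moved with them, with 11 of 14 higher and 0 lower, or 14 and 0 over the list alone (median 3.10, camera adjusted p = 6.13e-26, or 0.0515 with an estimated correlation). Macrophage markers had a median of 0.00 (camera adjusted p = 0.0587). Cell cycle genes were 11 lower of 22 after LPS and 0 higher, or 15 and 0 over the list alone (median -1.20, camera adjusted p = 1.88e-10, or 0.313 with an estimated correlation). Of 16 fibroblast markers Col1a1, Col1a2, Col6a3 and Fbln1 were lower after LPS and 0 higher (also over the list alone; median -1.65, camera adjusted p = 7.99e-05, or 0.597 with an estimated correlation). Antigen presentation had 5 genes higher, Tapbp, Psmb8, Psmb10, Nlrc5 and Cd274, and 0 lower, or 7 and 0 over the list alone (median 1.05, camera adjusted p = 2.98e-07, or 0.313 with an estimated correlation). Without 1 LPS or 2-week library at a time the called members numbered 6 to 10 for interferon-stimulated genes, 2 to 6 for NF-kB targets, 4 to 9 for cell cycle, 1 to 4 for fibroblast and 1 to 3 for antigen presentation genes. Among AT2 markers Hc was lower after LPS (log2 -2.04). The list median was 0.35 with a test upward (camera adjusted p = 0.0327, or 0.818 with an estimated correlation). That call was lost without LPS library 2 (0.0969) or 2-week library 1 (0.0600) and among genes of at least 5 FPKM (0.135), and the test turned downward with quantile normalization (0.959). Glycolysis (median 0.38, camera adjusted p = 0.000386), oxidative phosphorylation (0.39; 2.38e-05), unfolded protein response (0.35; 0.0063) and erythroid markers (2.11; 0.000158) were higher after LPS and mesothelial markers (-1.45; 0.00244) lower, with adjusted p = 0.213 to 0.825 with an estimated correlation. In these 5 lists limma called Slc16a3, a lactate transporter gene (log2 1.83), and Upk1b (-1.71). Hc, Slc16a3 and Upk1b were not called without LPS library 2 or 3 or any 1 of the 2-week libraries. Oxidative phosphorylation lost its call with quantile normalization (0.0679), unfolded protein response with that (0.146) and among genes of at least 5 FPKM (0.0814), and mesothelial markers without 4-week library 2 (0.0581).

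The calls against saline overlapped between treatments. Among 12320 genes tested in both, 676 rose after LPS and at 2 weeks of bleomycin, against 280.6 for independent sets of 1684 and 2053. Likewise 970 fell in both, against 392.5 for sets of 3232 and 1496, while 37 and 243 genes went opposite ways. The covariance of the fold changes was 0.193, against 0.0238 in 100 simulations of unchanged groups set against the same saline libraries, and their correlation across genes was 0.468 against a simulated 0.50. The share of genes with the same sign was 62.1%, below a simulated 66.6%. Without library 2, 91 of the 97 genes that rose at 4 weeks had also risen at 2 weeks, against 15.7 for independent sets, and 66 of the 80 that fell had also fallen, against 9.77 (covariance 0.0998, simulated 0.0169; correlation 0.587, simulated 0.452). Over all genes 61.4% had the same sign, below a simulated 64.8%. With no gene changed, the simulations shared 0 calls. How far the shared saline libraries add to the overlap of changed genes was thus not tested. The 3 saline libraries could not be divided into parts of 2.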

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

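The tests of a poorer depletion of all leukocytes, of dilution (with and without club cell markers) and of a lower AT2 share were chosen only after the result was seen, as were the values without library 2.

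Between 2 and 4 weeks of bleomycin, the direct test of the difference between the times called 67 genes (limma, fit of 12 libraries). Among the named genes it called Sftpc (log2 2.19), Cox6a2 (2.19) and Npw (1.95) as higher at 4 weeks and Arg1 (-2.83), Ccnb2 (-2.60) and Cdc20 (-2.52) as lower. Each of these 6 lost its call without any 1 of the 2-week libraries (adjusted p = 0.0623 to 0.353) and with the replicate number as a block (0.0523 to 0.0719), and Sftpc had a log2 fold change of 0.32 (adjusted p = 0.491) with quantile normalization. The lists that differed between the times were AT2 (median log2 fold change 0.31), club and goblet cell (0.15), cell cycle (-1.83), macrophage (-2.24) and mitochondrially encoded genes (-0.12, with a test upward). With an estimated correlation none of the 5 passed (adjusted p = 0.396 to 0.978), and with quantile normalization the club and goblet list (0.110) and the mitochondrial list (0.324) did not. These counts and medians include library 2 of the 4-week group, without which the test called 639 genes and the medians were 1.08, 0.69, -1.63, -1.38 and 0.95. Groups of 3 libraries are too small for a test of single outlying libraries.

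Library 2 of the 4-week group listed 45.4% of genes at 0. Broken RNA that loses long transcripts stays open. These had the higher share at 0 in 0 of 5 bins of expression, but yield more fragments at equal FPKM. A library made from few RNA molecules or reads may give such zeros: the share at 0 fell from 64.4% in the lowest bin to 16.7% in the highest, and in 5 of 5 bins it was lower for the longest than for the shortest tertile of transcripts (47.4% against 78.6% in the lowest). The test set in advance for a sample of another tissue could not decide. Of the 20 most abundant genes of library 2, 5 (Sec14l3, Gm9843, Emp2, Phlda1 and Gm10076) lay outside the 200 most abundant of the other 4-week libraries, at the edge of the bound. These 5 ranked 211 to 455 there. The top genes, Scgb1a1 (57536 FPKM), Sftpc (21625) and Sftpd (7656), ranked 1, 2 and 40 in the others, which argues against a tissue other than lung. No biological explanation was tested.

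Macrophage markers rose at 2 weeks in cells depleted with CD45 and CD16/32 antibodies, a step that would remove macrophages. A poorer depletion of all CD45-positive cells stays open, as the leukocyte mix at 2 weeks is unknown. 26 neutrophil and lymphocyte markers had a median log2 fold change of -0.11 against 1.91 for 17 macrophage markers (permutation p of list membership = 1e-05, the minimum). Macrophages carried through the depletion are a candidate source: 10 further genes abundant in leukocytes and macrophages (Tyrobp, Fcer1g, Laptm5, Coro1a, Cd53, Lcp1, Cd52, Lgmn, Ctsd and Apoe) had a median of 0.753 (SD 0.381, range 0.20 to 1.43), and 7 of them rose. Apoe and Ctsd are also made by other cell types, and Chil3, abundant in alveolar macrophages (143 and 155 FPKM), and Ptprc, the gene of CD45 (6.32 and 7.66 FPKM), did not pass (limma adjusted p = 0.794 and 0.319). Transcription of such genes in the treated epithelium itself stays open and untested.

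AT2 markers fell at 2 weeks, with a median of -1.51. Dilution of all epithelial cells by other cells stays open, since the permutations take genes as independent. 31 AT1 and ciliated markers had a median of -0.43 (permutation p of list membership = 1e-05, the minimum). The 12 club and goblet markers lay nearer, at -1.06 (permutation p = 0.0298, 3 lists together 1e-05). A lower share of AT2 cells would raise all other cell types alike, but their medians moved apart, from -1.06 for club and goblet markers, -0.45 for AT1, -0.38 for ciliated and -0.28 for endothelial markers to 0.71 for fibroblast and 1.91 for macrophage markers (permutation p = 1e-05). That result does not exclude a lower AT2 share together with a rise of macrophages and fibroblasts. Fewer surfactant transcripts in each AT2 cell after bleomycin may also have contributed, a hypothesis that these bulk libraries leave untested.

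Dividing the 6 libraries of each comparison in all 10 ways gives too few splits for a share under 0.05. The real counts of called genes and the highest of the other splits were 5002 and 1 for LPS against saline, 3786 and 2 for 2 weeks against saline, and 67 and 0 for 4 against 2 weeks. They were 484 and 0 for LPS against 2 weeks, and 0 and 0 for 4 weeks against saline (limma, 302 genes at an unadjusted p under 0.05, and 1 by the authors' q-values). A count as large came from 1 split in each of the first 4 of these, the real one, and from 10 of the 10 splits for 4 weeks against saline.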

How the results depend on the processing

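The tests chosen only after the result was seen were the fit of 11 libraries without 4-week library 2 and gene-by-gene array weights.

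Totals that moved by over 1.5 times, from 5002 genes (LPS against saline), 3786 (2 weeks against saline), 0 (4 weeks against saline), 67 (4 against 2 weeks) and 484 (LPS against 2 weeks), were as follows, and unless a reason is given the cause was not tested. Fewer genes tested (at least 5 FPKM) gave 3272 for LPS and 12 for 4 against 2 weeks, and a pseudocount of 0.1 gave 8 for the latter and 238 for LPS against 2 weeks. Scaling to equal totals gave 127 for 4 against 2 weeks, and quantile normalization gave 109 there and 1169 for LPS against 2 weeks. The stricter limit of a log2 change of at least 1 left 2029 for LPS and 716 for 2 weeks, and the authors' q-values gave 2857 for LPS and 1 for 4 weeks (C1qb). In 1 fit of 12 libraries, whose shared spread includes library 2, the totals were 669, 134 and 1 (Wfdc6b) against saline. The fit of 11 libraries gave 1773 for 2 weeks, 195 for 4 weeks, 639 for 4 against 2 weeks and 5764 for LPS against 2 weeks. Array weights gave 8315, 7030, 8257, 9974 and 8584, but their estimation converged only for LPS against saline, and splits that mixed the groups gave up to 8145, 7757 and 7443 in the comparisons with saline, so these weighted counts are no evidence of more changed genes. Gene by gene the weights gave 453 for 4 weeks (57 in a mixed split), 2873 for 4 against 2 weeks and 6477 for LPS against 2 weeks.

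Leaving out 1 library of the 2 groups compared at a time, and 4-week library 2 from both direct comparisons, the totals ranged from 2561 (without saline library 3) to 6693 (without LPS library 1) for LPS, and from 2153 (without 2-week library 3) to 3282 (without saline library 1) for 2 weeks. They ranged from 0 to 177 for 4 weeks (177 without library 2), from 1 (Tpx2, without 2-week library 2) to 639 (without 4-week library 2) for 4 against 2 weeks, and from 119 (without 2-week library 3) to 5764 (without 4-week library 2, with 452 without LPS library 1 next) for LPS against 2 weeks. Log2 fold changes at 4 weeks against saline ranged from -1.58 to 1.18 for Cxcl1, -1.59 to 1.21 for Fn1, -0.85 to 1.17 for Ccl2, -2.49 to 0.93 for Il6, -1.66 to 1.06 for Lum and -2.06 to 1.33 for Col3a1, each positive without library 2. S100g ranged from -1.85 to 2.18 at 4 against 2 weeks. The fit of 11 libraries likewise turned Cxcl1 (1.18) and Sdf2l1 (0.68) at 4 weeks and S100g (2.18) at 4 against 2 weeks. Quantile normalization turned Scgb1a1 at 2 weeks (0.12). It also turned the direction of the list test for mitochondrially encoded genes at 4 against 2 weeks (median -0.72, adjusted p = 0.324) and, between LPS and 2 weeks, for AT2 markers (median 0.054, test downward, adjusted p = 0.959) and immediate early genes (median -0.71, adjusted p = 0.0227, against a median of -0.04 and 0.755 before); the cause was not tested.

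The replicate numbers did not pair the libraries: residuals of libraries with the same number correlated at -0.156 to 0.265 between groups, and 0 to 2 libraries per pair of groups correlated best with their own number. With the replicate number as a block the totals were 4885, 3310 and 0 against saline, 371 for LPS against 2 weeks and 1 (Kif20a) for 4 against 2 weeks. That block leaves the unnumbered 4-week library without a partner.

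The alternatives counted here leave out array weights of both kinds, no trend, the size limit and the authors' q-values. Gene lists kept their side of the threshold in 493 of the list results for LPS, lost the call in 32 and gained it in 15. The numbers were 496, 40 and 19 for 2 weeks, 472, 33 and 47 for 4 weeks, 483, 14 and 28 for 4 against 2 weeks, and 475, 33 and 16 for LPS against 2 weeks. Named genes kept theirs in 1325 results for LPS (81 lost, 19 gained), 1269 for 2 weeks (107 and 23), 1506 for 4 weeks (0 lost by limma, where none was called, and 43 gained), 90 for 4 against 2 weeks (37 and 11) and 87 for LPS against 2 weeks (7 and 4). Of those lost, 46 for LPS and 58 for 2 weeks were lost in the fit of 12 libraries. Depth is unknown, so counting error and its effect on zeros and low genes cannot be given.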

Other observations

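The test of platelet genes, on a list that holds the genes that prompted it, and the tests without library 2 were chosen only after the result was seen.

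Most platelet genes tested were lower at 2 weeks of bleomycin than in saline. Of 8 platelet and megakaryocyte genes tested, 6 fell and 0 rose (median log2 fold change -0.90, camera p = 0.000204, or p = 0.185 with an estimated correlation). Ppbp, a platelet chemokine gene on chromosome 5 (90768518 to 90770063), fell from 19.6 ± 2.78 to 4.88 ± 0.416 FPKM (SD, n = 3 in each group; log2 -1.80 ± 0.12, limma adjusted p = 0.000168). Gp9 (log2 -1.68) and Gp5 (-0.88), of the platelet receptor for von Willebrand factor, Tubb1 (-1.37), a platelet tubulin, Treml1 (-0.91) and Itga2b (-0.60), an integrin of platelets, fell too. Pf4 (-0.03) and Gp1bb (0.79) did not pass (limma adjusted p = 0.928 and 0.0589). After LPS, Ppbp (log2 -1.18), Tubb1 (-1.29), Gp5 (-0.74) and Treml1 (-0.59) fell, Pf4 rose (2.10) and Gp9, Itga2b and Gp1bb did not pass (adjusted p = 0.061, 0.227 and 0.186). At 4 weeks without library 2, Ppbp (-1.93), Tubb1 (-1.95) and Gp5 (-1.01) fell and the other 5 did not pass (adjusted p = 0.0640 to 0.871).

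Transcripts that had changed at 2 weeks lay nearer to saline at 4 weeks, without library 2. Of the 2290 genes that had risen at 2 weeks, the 1983 also tested at 4 weeks had a median log2 fold change of 0.55 then and 0.12 at 4 weeks, and 66.6% of them still lay above saline. In the direct test 330 of them were lower at 4 than at 2 weeks and 2 higher. The 1496 genes that had fallen had medians of -0.56 and -0.37, and 86.6% still lay below saline, with 126 higher at 4 than at 2 weeks and 0 lower (limma, fit of 11 libraries). Because these genes were selected by their change at 2 weeks against the same saline libraries, part of the return toward saline can come from that selection, which was not simulated.

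After LPS and at 4 weeks of bleomycin without library 2, 33 genes rose in both, against 12.3 for independent sets, and 63 fell in both, against 21.2. The covariance of the fold changes was 0.0810 against a simulated 0.0254. Their correlation across genes was 0.280, below a simulated 0.447, 65.4% of genes had the same sign against a simulated 64.7%, and 4 genes that rose and 26 that fell after LPS went the opposite way at 4 weeks. With no gene changed, the simulations shared 0 calls and do not test what the shared saline libraries add.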
